A study of Nicotiana tabacum with 52 samples.

How the data were processed

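The series holds 52 arrays of 26 groups, 2 per group: total RNA, EPP, polysome and RNP fractions of 6 stages, and total RNA of leaf and root. Per the labels, labelled copies of 66 ng RNA per sample were hybridised to a one-colour tobacco oligonucleotide array with spike-in controls. The deposited scanner files hold spot brightness as intensity on a linear scale, which the authors made with Agilent Feature Extraction 10.5.1.1 or 11.0.1.1 under 3 protocols, with background subtraction and detrending and no normalization between arrays. Per the file headers, a flag is 0 or 1 and marks, among others, spots well above background. The deposited matrix holds intensity that the authors normalized in an unstated way, with 51.1% of its values at or below the floor of 4 and 21.6% below 0, and its rank correlation with the background-subtracted brightness of the same array ran from 0.840 to 0.996. It served as an alternative only.

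The processed brightness was taken to log2, spots marked as outliers (0 to 42 per array) were left out, and 44 duplicated spots were averaged, which gave 43759 probes from 43803 spots. Each array was centred on its 75th percentile over the 7616 probes well above background on all 52 arrays. Counts are of probes, not genes. Only 5025 probes had an informative description, 16014 were described as unknown and 16497 only by a sequence tag. Descriptions that matched a protein over less than 20%, or that gave only a locus, were treated as uninformative, a limit set after the files were opened and before any difference was computed. None of the array's accessions was in the reference table of genes, so names are those of the array annotation.

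Differences between groups came from limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table, version 1.17.8, in a single fit of all 26 groups with 26 residual degrees of freedom. A comparison tested the probes well above background on both arrays of at least 1 of its groups, with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05 on the adjusted p, two-sided. Comparisons were the 5 steps of total RNA from stage to stage, mature pollen against the mean of leaf and root, EPP and RNP each against polysomes at each of 6 stages, the 3 differences between fractions averaged over stages, the change of the EPP difference between mature pollen and 4 h tubes, and a moderated F test of that difference over 6 stages. A bound on a fold is the mean of the detected side against the level at which spots counted as detected. It is approximate, since the flag is set spot by spot.

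Before the data were examined, 21 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, on probes with informative descriptions, which departs from the fixed plan to search all descriptions. The lists covered cytosolic ribosomal proteins, translation factors, RNA-binding and RNA-processing proteins, actin cytoskeleton, tubulin and microtubule proteins, pectin and cell wall modification, ROP GTPase and calcium signalling, vesicle trafficking, named pollen proteins, tapetum and pollen wall precursors, photosynthesis, root nicotine pathway and root markers, histones and DNA replication, cyclins and cell division, heat shock proteins and chaperones, LEA and desiccation proteins, ubiquitin and proteasome, mitochondrial respiration, sugar and starch metabolism, lipid storage and synthesis, and transcription factors. Lists with fewer than 5 tested probes were not tested. Among probes that passed, and whose arrays of 1 group all lay above those of the other, the 3 largest rises and falls were named for a fraction at a single stage, and the first of the 10 largest for other comparisons. For the averages, the sign had to be the same at all 6 stages. Up to 4 passing members were named per list. NTP303, Actin-97, profilin and pectate lyase were followed whatever their values.

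Alternatives were quantile normalization, normexp background correction (offset 50), the 75th percentile over all probes, the spike-in controls (320 spots, 10 levels) as scale, the deposited matrix, no filter and a stricter filter on dim probes, a minimum log2 of 1, array weights, only the groups of the comparison in the fit, slide as a random block, the replicate number as a block, and each array left out in turn, where the lone array was assumed to vary like the other groups. Slide as a fixed block, the averages without microspores, and a fit without the microspore fractions were added after the data were seen. Scan day as a block could not be fitted, since each group was scanned on 1 day. The arrays came from 13 slides, 5 scan days and 4 runs: mature pollen and 4 h tubes in the first, leaf and root in the second, 24 h tubes in the third, and microspores and bicellular pollen in the fourth. Other groupings of the arrays were made by exchanging EPP, RNP and polysome arrays within stages, 100 in all per average, the real one included. Of 200 simulated probes changed by 1 log2, 27% were found for a total RNA step and 26% for a fraction at 1 stage. A 6-stage average gave 75% and the change of a difference 6.5%. False calls were 2.75% to 4.87% of calls, which need not hold for real arrays of unequal weight.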

Results

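RNA from developing tobacco pollen and growing pollen tubes was measured on 52 one-colour oligonucleotide arrays. The 6 stages were microspores, early bicellular pollen, late bicellular pollen, mature pollen, and pollen tubes grown for 4 h or 24 h. At each stage total RNA and 3 fractions were hybridised, namely polysomes (ribosomes on messenger RNA), free ribonucleoprotein particles (RNP), and the particles the labels call EPP, which in work on tobacco pollen are storage particles that survive when polysomes are taken apart. Total RNA of leaf and of root served as tissues without pollen. Each of the 26 groups had 2 arrays, given as 2 biological replicates. Every value below rests on n = 2 per group and every p-value of a probe on the spread between samples. A p-value of a gene list sets it against the other probes at a preset correlation between genes, unless an estimated one is named.

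Between 12638 and 34930 of 43759 probes lay well above background on an array, with a median of 20142.5. Probes above background on both arrays numbered 28208 in leaf and 27903 in root, 16660 in total RNA of microspores, 13937 in that of mature pollen, and 11896 in polysomes of 24 h tubes, the fewest of any group. Replicate arrays correlated across probes (probes are not independent replicates) at 0.944 to 0.998 in 23 groups, and at 0.868 for polysomes of microspores, 0.877 for total RNA of mature pollen and 0.91 for RNP of microspores. The number of arrays and the pooling of their spread limit the precision. Standard errors of a difference between 2 fractions of 1 stage were 0.47 for NTP303, 0.29 for Actin-97, 0.18 for profilin and 0.49 for pectate lyase, 4 genes followed throughout, and are not repeated. Differences are in log2 of scaled intensity, followed by ± the standard error. Where 1 side lay at background on all its arrays, an approximate bound such as "at least N-fold" is given instead. It is taken from the brighter side and the level at which a probe counts as detected. Gene lists are described by their relative median, the median log2 difference less that of all tested probes, since another scaling moved the median of all probes by over 0.1 log2 in most comparisons. Brackets after a count give the lowest and highest on other settings of scaling, filter or fit, where over 1.5 times away and not 0. A direction is said to turn on another scaling only with medians matched, that is, after the median of all tested probes there was set to that of the main scaling.

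**Figure D1:**
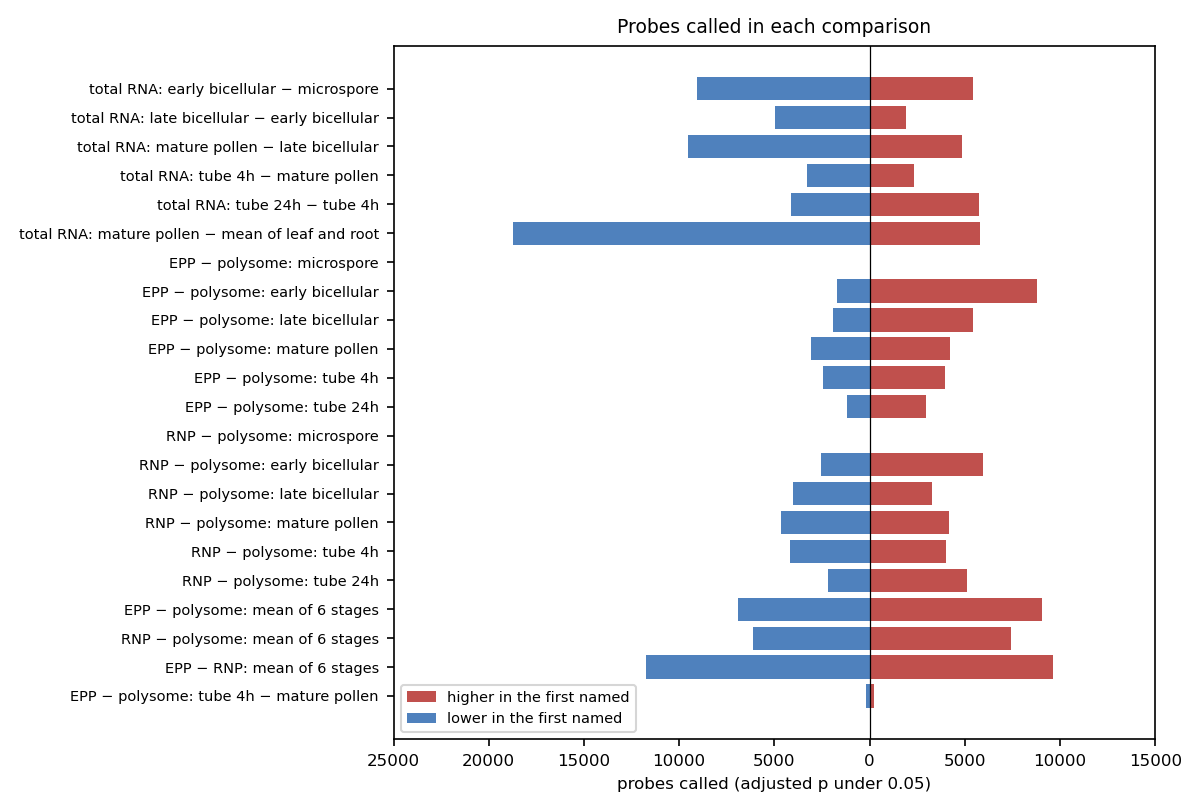
Number of probes higher or lower (adjusted p under 0.05, limma) in each comparison of 2 groups of 2 arrays, and in mature pollen against the mean of leaf and root. Early bicellular pollen against microspores gave 14491 probes, while EPP and RNP against polysomes in microspores gave 4 and 3.

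From microspores to early bicellular pollen, the step around the first pollen mitosis, 14491 of 23839 probes (8144 with normexp and 30991 with no filter on dim probes) changed in total RNA, 5407 higher and 9084 lower. Rises included a pollen coat-like protein (at least 568-fold higher), the pectin methylesterase PPME1 (at least 289-fold higher), which loosens or stiffens pectin in the wall, and phosphoenolpyruvate carboxykinase (at least 220-fold higher). Protein 108 (-11.79 ± 0.50, adjusted p = 1.44e-17), an anther protein, a phenylcoumaran benzylic ether reductase (at least 617-fold lower) and an arabinogalactan protein (at least 213-fold lower) fell. Of 21 named pollen protein probes, 15 were higher and 3 lower (15 and 3 adjusted over the list alone), with a relative median of 5.18 (adjusted p = 6.42e-05, and adjusted p = 0.0533 with an estimated correlation). A B-type cyclin (at least 61.9-fold lower), of mitosis, fell. Of 76 mitochondrial respiration probes, 62 were higher and 6 lower (64 and 7 adjusted over the list alone), with a relative median of 2.07 (adjusted p = 4.2e-15, and adjusted p = 0.0256 with an estimated correlation). They included a cytochrome c oxidase family protein (3.69 ± 0.22).

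The followed genes had 7.45 ± 0.47 for NTP303, 2.10 ± 0.29 for Actin-97, -0.62 ± 0.18 for profilin and 4.74 ± 0.49 for pectate lyase (adjusted p = 9.99e-14, 4.26e-07, 0.00489 and 2.42e-09), but with medians matched profilin 0.12 with normexp background correction. Of 49 photosynthesis probes, 9 were higher and 37 lower (9 and 37 adjusted over the list alone), with a relative median of -2.38 (adjusted p = 0.00183, and adjusted p = 0.382 with an estimated correlation). Of 13 tapetum and pollen wall probes, 0 were higher and 10 lower (1 and 10 adjusted over the list alone), with a relative median of -2.20 (adjusted p = 0.0391, and adjusted p = 0.12 with an estimated correlation). The latter list held mostly lipid-transfer proteins such as non-specific lipid-transfer protein B (at least 18.1-fold lower) and the auxin-response protein IAA9. It held no strict tapetum marker, so it says little about anther cells. In this step 37.3% of calls were higher (22.6% with normexp and 91.7% with spike-in scaling), and rescaling moved the median probe by -0.76 to 2.31. The threshold was missed by profilin without microspore total replicate 1 (adjusted p = 0.0793) and early bicellular total replicate 2 (adjusted p = 0.073).

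Late bicellular pollen differed from early bicellular pollen in 6850 of 23190 probes (840 with normexp and 13377 with array weights), 1902 higher and 4948 lower. Rises included late embryogenesis abundant protein 5 (7.98 ± 0.34, adjusted p = 6.03e-17), phosphoglycerate dehydrogenase (6.86 ± 0.19) of serine synthesis, pectate lyase P59 (6.29 ± 0.64) and NTS1 (at least 21.3-fold higher). Chromatin proteins fell, with histone H2A (-5.42 ± 0.58) and histone H2B (-4.73 ± 0.58), and so did an RNA-binding glycine-rich protein (at least 17.4-fold lower). Of 45 histone and DNA replication probes, 0 were higher and 35 lower (0 and 37 adjusted over the list alone), with a relative median of -1.78 (adjusted p = 2.88e-14, and adjusted p = 0.104 with an estimated correlation). Of 30 actin cytoskeleton probes, 11 were higher and 6 lower (11 and 6 adjusted over the list alone), with a relative median of 0.62 (adjusted p = 0.00123, and adjusted p = 0.0179 with an estimated correlation). Examples were a pollen LIM domain protein (4.04 ± 0.71), which binds actin filaments, and actin-depolymerizing factor 2 (3.18 ± 0.44). Of 63 vesicle trafficking probes, 17 were higher and 4 lower (17 and 4 adjusted over the list alone), with a relative median of 0.49 (adjusted p = 2.14e-05, and adjusted p = 0.0348 with an estimated correlation).

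Values of the 4 followed genes were 0.47 ± 0.47 for NTP303, 1.11 ± 0.29 for Actin-97, 0.31 ± 0.18 for profilin and 3.11 ± 0.49 for pectate lyase (adjusted p = 0.528, 0.00418, 0.222 and 1.66e-05). For the late step 27.8% of calls were higher (17.6% with spike-in scaling and 57.3% with normexp), and rescaling moved the median probe by -0.19 to 0.35. For late bicellular pollen the count was 3857 without early bicellular total replicate 2 and 4141 without late bicellular total replicate 1.

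Between late bicellular and mature pollen 14395 of 21049 probes (8013 with a stricter filter on dim probes) changed, 4874 higher and 9521 lower. NtEIG-E80 (11.22 ± 0.54, adjusted p = 5.89e-16), known in elicitor responses, aromatic amino acid decarboxylase 2 (8.31 ± 0.52) and another late embryogenesis abundant protein 5 probe (7.69 ± 0.54) rose. Prolyl 4-hydroxylase (at least 147-fold lower), which modifies wall proteins, a receptor-like protein kinase (-7.10 ± 0.78) and STS14 (at least 117-fold lower) fell. Of 221 cytosolic ribosomal protein probes, 8 were higher and 189 lower (9 and 190 adjusted over the list alone), with a relative median of -1.41 (adjusted p = 5.6e-13, and adjusted p = 0.415 with an estimated correlation). Of 64 heat shock and chaperone probes, 11 were higher and 42 lower (11 and 42 adjusted over the list alone), with a relative median of -0.70 (adjusted p = 0.0111, and adjusted p = 0.415 with an estimated correlation). The fall included mitochondrial chaperonin CPN60-1 (-4.75 ± 0.37) and calreticulin (-3.81 ± 0.44).

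Maturation gave 2.30 ± 0.47 for NTP303 and 4.39 ± 0.29 for Actin-97 (adjusted p = 0.000105 and 3.47e-13). It gave 0.50 ± 0.18 for profilin and 2.14 ± 0.49 for pectate lyase (adjusted p = 0.0175 and 0.00039). Errors pool all groups, but Actin-97 on mature arrays had an SD of 1.26 (others at most 0.37). With medians matched, NTP303 and pectate lyase were -1.13 and -0.95 with quantile normalization. Likewise NTP303, profilin and pectate lyase were -0.91, -1.70 and -1.16 with normexp, and -0.76, -0.32 and -1.18 with the deposited matrix. On maturation 33.9% of calls were higher (6.39% with spike-in scaling and 92.4% with normexp), and rescaling moved the median probe by -1.70 to 2.33. These stages were scanned in different runs, and no stage was in both, so run and stage cannot be told apart. No probe passed in limma with only its own groups in the fit (7582 at unadjusted p under 0.05). Calls were lost for profilin without late bicellular total replicate 2 (adjusted p = 0.0937).

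After 4 h of growth, tubes differed from mature pollen in 5624 of 15775 probes (556 with slide as a fixed block), 2314 higher and 3310 lower. A probe described as Avr9 (4.85 ± 0.44, adjusted p = 1.47e-09) and the calmodulin NtCaM1 (at least 6.16-fold higher), a calcium sensor, were higher. So were the transcription factor NtWRKY-6 (at least 3.2-fold higher) and luminal-binding protein 8 (3.66 ± 0.19), a chaperone of the endoplasmic reticulum. The sucrose transporter (-5.75 ± 0.56), dehydration-responsive element binding protein 3 (at least 9.02-fold lower) and a mitochondrial carnitine carrier (-4.79 ± 0.48) were lower. Of 58 heat shock and chaperone probes, 22 were higher and 5 lower (22 and 5 adjusted over the list alone), with a relative median of 0.53 (adjusted p = 0.000115, and adjusted p = 0.691 with an estimated correlation). Luminal-binding protein again led, with blp4 (2.90 ± 0.20). Of 37 histone and DNA replication probes, 16 were higher and 5 lower (18 and 5 adjusted over the list alone), with a relative median of 0.84 (adjusted p = 0.000115, and adjusted p = 0.738 with an estimated correlation). Followed genes gave 0.06 ± 0.47 for NTP303, -2.05 ± 0.29 for Actin-97, 1.34 ± 0.18 for profilin and 1.07 ± 0.49 for pectate lyase (adjusted p = 0.935, 2.58e-06, 1.43e-06 and 0.091). Between mature pollen and 4 h tubes 41.1% of calls were higher (13% with spike-in scaling and 68.9% with scaling over all probes), and rescaling moved the median probe by -0.67 to 0.43. No probe passed in limma with only its own groups in the fit (882 at unadjusted p under 0.05). Without mature pollen total replicate 2, a mitochondrial carnitine carrier had -3.10 and Actin-97 had -1.16.

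Tubes at 24 h differed from tubes at 4 h in 9887 of 15989 probes (2060 with normexp), 5738 higher and 4149 lower. Hairy root 4 (at least 10220-fold higher), phosphoenolpyruvate carboxylase (at least 7.81-fold higher), sucrose synthase (5.06 ± 0.41, adjusted p = 6.95e-11), which supplies sugar for wall synthesis, and the chaperone Hsc70 (at least 16.3-fold higher) were higher. An early light inducible protein (at least 17.9-fold lower), 40S ribosomal protein S24-1 (-5.10 ± 0.23) and the pollen coat-like protein (-4.41 ± 0.57) were lower. Of 194 cytosolic ribosomal protein probes, 11 were higher and 128 lower (11 and 133 adjusted over the list alone), with a relative median of -1.29 (adjusted p = 1.84e-16, and adjusted p = 0.699 with an estimated correlation). Of 59 RNA-binding and RNA-processing probes, 37 were higher and 9 lower (37 and 9 adjusted over the list alone), with a relative median of 0.78 (adjusted p = 0.0102, and adjusted p = 0.699 with an estimated correlation). Its members moved both ways, from RNA-binding glycine-rich protein 1 (3.67 ± 0.41) to small nuclear ribonucleoprotein F (at least 4.36-fold lower). At 24 h the followed genes gave 0.56 ± 0.47 for NTP303, 1.04 ± 0.29 for Actin-97, 0.38 ± 0.18 for profilin and 0.40 ± 0.49 for pectate lyase (adjusted p = 0.306, 0.00313, 0.0735 and 0.485). Between the tube ages 58% of calls were higher (15.9% with spike-in scaling and 54.8% with the deposited matrix), and rescaling moved the median probe by -0.90 to -0.14. The tube ages were scanned in different runs, which cannot be told apart from age.

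Mature pollen differed from the mean of leaf and root in 24526 of 30671 probes (10021 with a stricter filter on dim probes), 5811 higher and 18715 lower. Pollen held arabinogalactan peptide 13 (at least 129000-fold higher), a pollen LIM domain protein (at least 75330-fold higher) and PPME1 (at least 35550-fold higher), all at background in leaf and root. NTP303, a pollen tube wall glycoprotein, was higher by 13.53 ± 0.41 (adjusted p = 6.05e-22) and pectate lyase by 14.20 ± 0.43. Actin-97 was higher by 5.65 ± 0.25 (pooled, SD 1.26 in pollen) and profilin lower (-0.98 ± 0.16). It held less of catalase CAT-1 (at least 2570-fold lower), an extensin (at least 776-fold lower) and a basic chitinase (at least 437-fold lower), a defence protein. Of 21 named pollen protein probes, 13 were higher and 7 lower (13 and 7 adjusted over the list alone), with a relative median of 14.53 (adjusted p = 2.73e-05, and adjusted p = 0.071 with an estimated correlation). Of 91 photosynthesis probes, 2 were higher and 86 lower (2 and 87 adjusted over the list alone), with a relative median of -2.46 (adjusted p = 2.73e-05, and adjusted p = 0.501 with an estimated correlation). They were led by Rubisco activase (at least 178-fold lower). Of 156 transcription factor probes, 13 were higher and 127 lower (13 and 127 adjusted over the list alone), with a relative median of -1.75 (adjusted p = 0.00502, and adjusted p = 0.766 with an estimated correlation). Of 18 tapetum and pollen wall probes, 0 were higher and 18 lower (0 and 18 adjusted over the list alone), with a relative median of -3.13 (adjusted p = 0.00202, and adjusted p = 0.071 with an estimated correlation).

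In mature pollen against leaf and root 23.7% of calls were higher (27.5% with spike-in scaling and 80.2% with normexp), and rescaling moved the median probe by 0.39 to 2.74. With normexp background correction 15543 probes were called, 12471 of them higher in pollen, and 4162 of those (33.4%) were not above background in pollen. The tissues were scanned in different runs, which cannot be told apart from tissue.

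**Figure D2:**
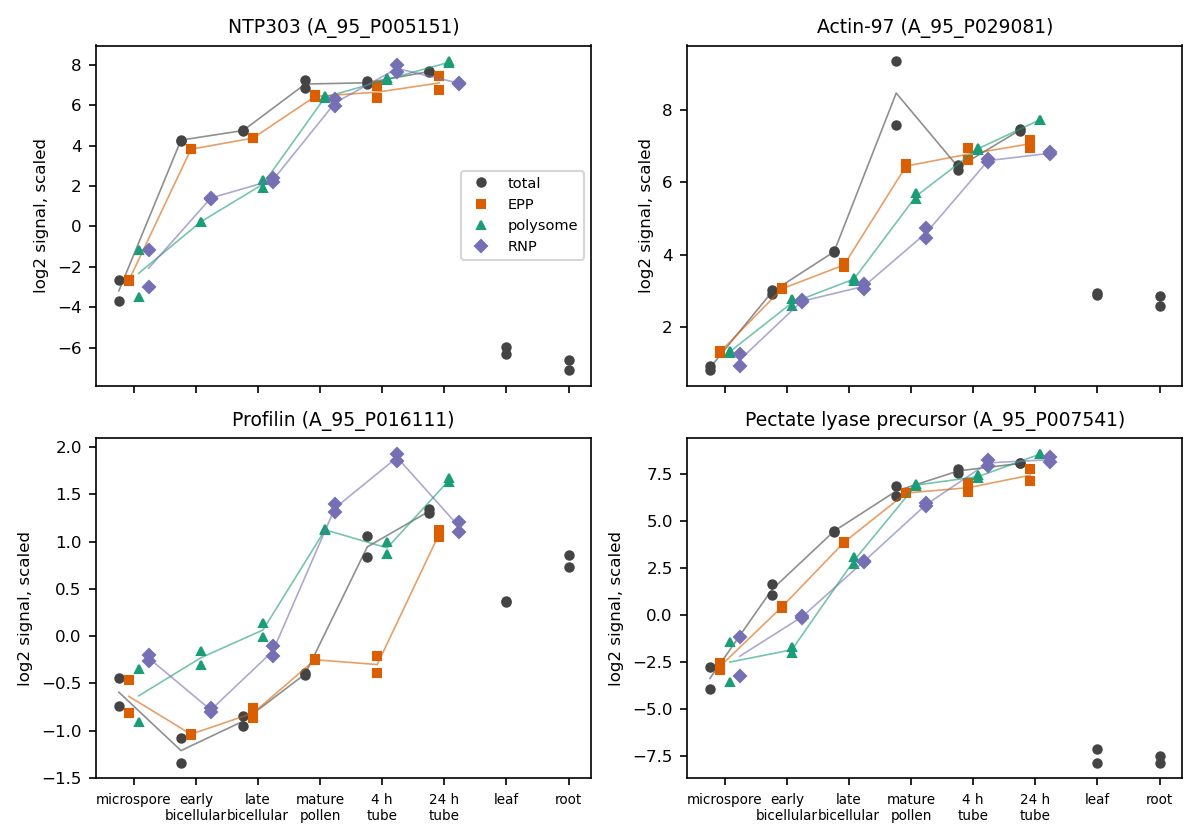
Scaled log2 intensity of NTP303, Actin-97, profilin and pectate lyase (vertical axes) in each group of 2 arrays (points) with their mean, by stage and fraction. NTP303 in total RNA was -3.18 in microspores and 4.27 in early bicellular pollen on the scaling used throughout. With medians matched its later step to mature pollen turned with quantile normalization, normexp background correction and the deposited matrix.

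Comparing each particle fraction with polysomes gives their relative composition on a chosen scaling, not how a transcript is split between storage and translation. In microspores EPP differed from polysomes in 4 of 26884 probes and RNP in 3 of 27653, all named here because they are few, after their values were seen. For EPP these were A_95_P265131 (-3.37 ± 0.51, adjusted p = 0.0031), A_95_P094408 (-2.80 ± 0.29, adjusted p = 3.49e-06) and A_95_P149177 (-2.27 ± 0.33, adjusted p = 0.0017), lower, and A_95_P316528 (2.69 ± 0.49, adjusted p = 0.0458), higher, none with a known product. For RNP they were A_95_P094408 (-1.71 ± 0.29, adjusted p = 0.0277), A_95_P163517 (-1.12 ± 0.18, adjusted p = 0.0277) and A_95_P115242 (-1.40 ± 0.25, adjusted p = 0.0378), the last being RhoGAP1, which switches off ROP GTPases. For EPP the followed genes gave -0.36 for NTP303, -0.01 for Actin-97, -0.01 for profilin and -0.24 for pectate lyase (adjusted p = 0.856, 0.994, 0.995 and 0.916). For RNP they gave 0.25 for NTP303, -0.23 for Actin-97, 0.40 for profilin and 0.31 for pectate lyase (adjusted p = 0.801, 0.705, 0.357 and 0.76). Without adjustment, limma gave p under 0.05 for 2649 probes for EPP and 3629 for RNP. The libraries labelled polysome replicate 2 and RNP replicate 1 correlated across probes at 0.982, against 0.839 between the libraries labelled polysome. Rescaling moved the median of all probes by -0.19 to 0.24 log2 for EPP and -0.30 to 0.68 for RNP. The EPP count was 2396 without microspore EPP replicate 1, 1 without microspore EPP replicate 2 and 3939 without microspore polysome replicate 1. The RNP count was 0 to 2758 with any 1 of its 4 arrays left out. The deposited matrix called 846 and 726, and several other settings no probe. RhoGAP1 lost its call without microspore polysome replicate 1 (-1.42) and without microspore RNP replicate 1 (-0.89).

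**Figure D3:**
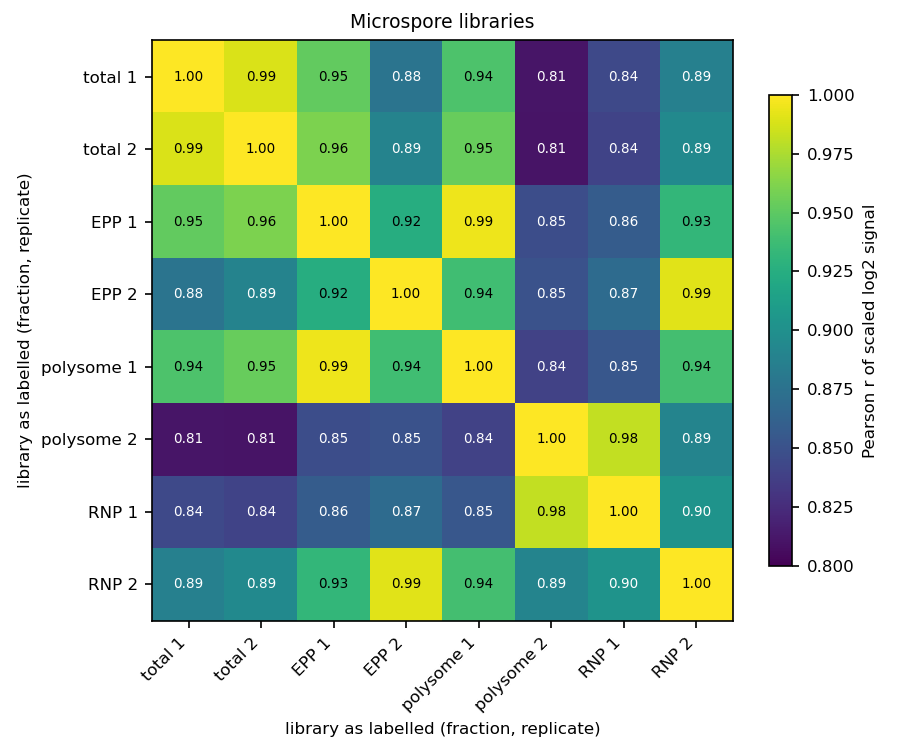
Pearson correlation across 16463 probes between each pair of the 8 microspore libraries, by their deposited labels. The library labelled EPP replicate 1 lay closest to polysome replicate 1 (0.995), EPP replicate 2 to RNP replicate 2 (0.991), and polysome replicate 2 to RNP replicate 1 (0.982).

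In early bicellular pollen EPP and polysomes differed in 10521 of 23972 probes (1491 with normexp), 8794 higher and 1727 lower in EPP. EPP held more of an mRNA-binding protein (4.16 ± 0.84), thioredoxin (4.02 ± 0.74) and a probe described as WSSV375 (at least 6.05-fold higher), and less of the pollen calcium-dependent kinase Nict2 (-2.39 ± 0.58, adjusted p = 0.00182), vetispiradiene synthase (at least 1.83-fold lower, but 0.10 with normexp background correction and 0.48 with the deposited matrix and medians matched) and a glucosyltransferase (-2.39 ± 0.56). Of 148 ubiquitin and proteasome probes, 23 were higher and 14 lower (19 and 13 adjusted over the list alone), with a relative median of -0.61 (adjusted p = 0.000129, and adjusted p = 0.0112 with an estimated correlation). Single members such as the E3 ligase CIP8 (2.60 ± 0.43) were higher. In early EPP the followed genes gave 3.58 for NTP303, 0.39 for Actin-97, -0.81 for profilin and 2.29 for pectate lyase (adjusted p = 5.01e-06, 0.279, 0.000994 and 0.000638). For this stage 83.6% of calls were higher (7.91% with spike-in scaling and 68.2% with normexp), and rescaling moved the median probe by -1.45 to -0.04. The early EPP count was 6786 without early bicellular EPP replicate 1, 6643 without early bicellular EPP replicate 2 and 6140 without early bicellular polysome replicate 2.

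Late bicellular EPP differed from polysomes in 7356 of 20156 probes (965 with normexp and 13517 with array weights), 5444 higher and 1912 lower in EPP. Cysteine-rich extensin-like protein 2 (at least 3.54-fold higher), a light-harvesting protein (at least 5.81-fold higher) and ALG2-interacting protein X (3.68 ± 0.68, adjusted p = 0.000195), which acts in membrane sorting, were higher, and calcineurin B-like protein 4-1 (at least 1.75-fold lower) and chloroplast ribosomal protein S16 (-2.50 ± 0.59) lower. Of 144 ubiquitin and proteasome probes, 11 were higher and 17 lower (11 and 16 adjusted over the list alone), with a relative median of -0.53 (adjusted p = 0.000346, and adjusted p = 0.0318 with an estimated correlation). Of 33 tubulin and microtubule probes, 17 were higher and 2 lower (19 and 2 adjusted over the list alone), with a relative median of 0.46 (adjusted p = 0.0129, and adjusted p = 0.51 with an estimated correlation). They included an internal-motor kinesin (1.95 ± 0.55) and a BY-2 kinesin-like protein (1.61 ± 0.33). Late EPP gave 2.28 for NTP303, 0.39 for Actin-97, -0.88 for profilin and 0.97 for pectate lyase (adjusted p = 0.000563, 0.289, 0.000585 and 0.12). In late bicellular EPP 74% of calls were higher (35% with scaling over all probes and 52.4% with normexp), and rescaling moved the median probe by -0.56 to 0.12. Late EPP counts were 3656 to 4855 with any 1 of its 4 arrays left out. The threshold was missed by an internal-motor kinesin without late bicellular EPP replicate 1 (adjusted p = 0.0592).

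In mature pollen 7259 of 20375 probes (24687 with no filter on dim probes) differed between EPP and polysomes, 4202 higher and 3057 lower in EPP. A glycine-rich protein-like transcript (3.95 ± 0.28, adjusted p = 3e-10), NADPH-cytochrome P450 oxidoreductase (at least 5.39-fold higher) and a phosphosulfolactate synthase-related protein (3.38 ± 0.31) were higher in EPP, and a diphenol oxidase (-4.54 ± 0.41), chloroplast ribosomal protein S16 (-4.35 ± 0.59) and nucleobase-ascorbate transporter 6 (-4.25 ± 0.53) lower. Of 10 LEA and desiccation protein probes, 0 were higher and 7 lower (0 and 7 adjusted over the list alone), with a relative median of -1.59 (adjusted p = 0.000759, and adjusted p = 0.00673 with an estimated correlation, but 0.111 with no filter). A LEA1-like protein (-1.66 ± 0.30) and a dehydrin-like protein (-1.44 ± 0.20, but 0.0202 with normexp background correction and medians matched) were among those lower. Of 66 heat shock and chaperone probes, 29 were higher and 6 lower (32 and 7 adjusted over the list alone), with a relative median of 0.57 (adjusted p = 0.000612, and adjusted p = 0.307 with an estimated correlation). Heat shock protein 90 (2.82 ± 0.26) and a mitochondrial small heat shock protein (3.24 ± 0.45) led it. Mature EPP gave 0.04 for NTP303, 0.83 for Actin-97, -1.38 for profilin and -0.42 for pectate lyase (adjusted p = 0.957, 0.0259, 1.97e-06 and 0.541), but with medians matched profilin 0.13 with normexp background correction. In mature EPP 57.9% of calls were higher (8.42% with normexp and 99.8% with spike-in scaling), and rescaling moved the median probe by -1.42 to 3.40. The mature EPP count was 4430 without mature pollen EPP replicate 1 and 4669 without mature pollen polysome replicate 1. No probe passed in limma with slide as a fixed block (5552 at unadjusted p under 0.05). Calls were lost for Actin-97 without any 1 of the 4 arrays (adjusted p = 0.0626 to 0.137).

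In 4 h tubes EPP differed from polysomes in 6448 of 20568 probes (752 with normexp and 16422 with spike-in scaling), 3982 higher and 2466 lower in EPP. EPP held more of Avr9 (at least 2-fold higher), soluble starch synthase 3 (at least 1.57-fold higher) and a reverse transcriptase polypeptide (3.09 ± 0.76), and less of chloroplast ribosomal protein S16 (-3.92 ± 0.59, adjusted p = 2.81e-05), the early light inducible protein (-3.28 ± 0.89) and glutaredoxin (-2.97 ± 0.32). Of 137 ubiquitin and proteasome probes, 15 were higher and 33 lower (15 and 34 adjusted over the list alone), with a relative median of -0.58 (adjusted p = 0.00011, and adjusted p = 0.042 with an estimated correlation, but 0.0982 with no filter). Ubiquitin-fold modifier 1 (-2.10 ± 0.32) was lower and a ubiquitin carrier protein (2.05 ± 0.51) higher. In EPP of 4 h tubes values were -0.63 for NTP303, -0.15 for Actin-97, -1.24 for profilin and -0.59 for pectate lyase (adjusted p = 0.309, 0.716, 2.19e-05 and 0.365). At 4 h 61.8% of calls were higher (13.2% with normexp and 99.9% with spike-in scaling), and rescaling moved the median probe by -0.70 to 1.79. Counts at 4 h were 1825 without 4 h tube EPP replicate 1, 4061 without 4 h tube polysome replicate 1 and 3029 without 4 h tube polysome replicate 2. No probe passed in limma with only its own groups in the fit (8607 at unadjusted p under 0.05) or slide as a fixed block (5027 at unadjusted p under 0.05). Without 4 h tube EPP replicate 1, Avr9, a reverse transcriptase polypeptide, the early light inducible protein and a ubiquitin carrier protein lost their calls. The early light inducible protein was also lost without 4 h tube polysome replicate 2. Soluble starch synthase 3 was lost without 4 h tube EPP replicate 2.

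By 24 h 4144 of 16330 probes (91 with normexp and 17336 with no filter on dim probes) differed between EPP and polysomes, 2976 higher and 1168 lower in EPP. Phospholipase C2 (at least 2.29-fold higher), a lipid signalling enzyme, NADH dehydrogenase subunit 5 (at least 2.63-fold higher) and the reverse transcriptase polypeptide (3.84 ± 0.76) were higher, and a photosystem II polypeptide (at least 7.1-fold lower), nucleobase-ascorbate transporter 6 (-3.18 ± 0.53) and the diphenol oxidase (-3.04 ± 0.41, adjusted p = 5.87e-06) lower. Of 129 ubiquitin and proteasome probes, 6 were higher and 22 lower (5 and 20 adjusted over the list alone), with a relative median of -0.42 but 0.0733 with normexp background correction (adjusted p = 2.59e-05, and adjusted p = 0.00451 with an estimated correlation, but 0.562 with no filter). Of 57 vesicle trafficking probes, 0 were higher and 11 lower (0 and 11 adjusted over the list alone), with a relative median of -0.42 but 0.30 with normexp background correction (adjusted p = 2.7e-05, and adjusted p = 0.0486 with an estimated correlation, but 0.935 with normexp and 0.603 with no filter). Lower members included the GTPase Sar1BNt (-0.98 ± 0.24, but 0.0503 with normexp background correction and medians matched) of vesicle budding. EPP of 24 h tubes gave -1.02 for NTP303, -0.67 for Actin-97, -0.57 for profilin and -1.13 for pectate lyase (adjusted p = 0.111, 0.0903, 0.0238 and 0.0923), but with medians matched profilin 0.43 with normexp background correction. In 24 h EPP 71.8% of calls were higher (23.1% with normexp and 99.9% with spike-in scaling), and rescaling moved the median probe by -0.89 to 2.49. In EPP of 24 h tubes the count was 1724 to 2463 with any 1 of its 4 arrays left out. The threshold was missed by profilin without any 1 of the 4 arrays (adjusted p = 0.0766 to 0.14).

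RNP of early bicellular pollen differed from polysomes in 8475 of 26416 probes (1071 with normexp and 17117 with array weights), 5931 higher and 2544 lower in RNP. Transcripts described as a copia-type reverse transcriptase (at least 31.6-fold higher), integrase (6.15 ± 0.74, adjusted p = 1.59e-06) and a putative translation transactivator (6.0 ± 0.97) were higher, and dehydroascorbate reductase (-3.04 ± 0.43), ferulate-5-hydroxylase (-2.41 ± 0.42) and the multifunctional protein NtMFP (-2.39 ± 0.49) lower. Of 47 histone and DNA replication probes, 1 was higher and 31 lower (1 and 34 adjusted over the list alone), with a relative median of -1.46 (adjusted p = 1.64e-14, and adjusted p = 0.214 with an estimated correlation). They included histone H4 (-2.33 ± 0.38) and histone H2A (-2.06 ± 0.43). Early RNP gave 1.17 for NTP303, 0.04 for Actin-97, -0.55 for profilin and 1.75 for pectate lyase (adjusted p = 0.0568, 0.919, 0.022 and 0.00816). In early RNP 70% of calls were higher (18.4% with spike-in scaling and 74.3% with normexp), and rescaling moved the median probe by -1.08 to 0.30. The early RNP count was 4365 to 4814 with any 1 of its 4 arrays left out. Calls were lost for profilin without any 1 of the 4 arrays (-0.62 to -0.48). Pectate lyase was lost without early bicellular polysome replicate 1 (1.58) or RNP replicate 1 (1.72).

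Late bicellular RNP and polysomes differed in 7328 of 18703 probes (1108 with normexp), 3283 higher and 4045 lower in RNP. ORF45 (5.65 ± 0.98), a glucosyltransferase (4.39 ± 0.49, adjusted p = 1.86e-07) and a cell wall protein (at least 3.94-fold higher) were higher, and dehydroascorbate reductase (-3.36 ± 0.43), a short-chain dehydrogenase (at least 2.73-fold lower) and the initiation factor NeIF-4A9 (-3.18 ± 0.60) lower. Of 40 histone and DNA replication probes, 1 was higher and 16 lower (1 and 16 adjusted over the list alone), with a relative median of -0.64 (adjusted p = 0.00304, and adjusted p = 0.94 with an estimated correlation). Histone H3 (-1.88 ± 0.46) was lower while histone H1 (2.08 ± 0.34) was higher. Late RNP gave 0.20 for NTP303, -0.20 for Actin-97, -0.22 for profilin and -0.05 for pectate lyase (adjusted p = 0.752, 0.6, 0.343 and 0.944). In late RNP 44.8% of calls were higher (21.3% with spike-in scaling and 62.5% with normexp), and rescaling moved the median probe by -0.44 to 0.30. The late RNP count was 4725 without late bicellular polysome replicate 1, 4755 without late bicellular polysome replicate 2 and 4785 without late bicellular RNP replicate 1.

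In mature pollen RNP differed from polysomes in 8827 of 16200 probes (1040 with normexp), 4170 higher and 4657 lower in RNP. RNP held more of ATP synthase subunit a (4.89 ± 0.47, adjusted p = 3.23e-09), apocytochrome b (4.76 ± 0.38) and the psaC product (4.42 ± 0.54), all encoded in organelles, and less of delta-tonoplast intrinsic protein (at least 6.88-fold lower), a water channel, a CXE carboxylesterase (-4.17 ± 0.86) and Bypass1 (-3.83 ± 0.47). Of 56 heat shock and chaperone probes, 26 were higher and 6 lower (26 and 6 adjusted over the list alone), with a relative median of 0.70 (adjusted p = 0.000985, and adjusted p = 0.334 with an estimated correlation). Small heat shock protein HSP17.6 (3.11 ± 0.55) and heat shock protein 90 (2.09 ± 0.26) were higher. Of 9 LEA and desiccation protein probes, 0 were higher and 6 lower (0 and 6 adjusted over the list alone), with a relative median of -1.11 (adjusted p = 0.0471, and adjusted p = 0.0952 with an estimated correlation, but 0.0861 with quantile, 0.0686 with normexp and 0.0681 with scaling over all probes). Mature RNP gave -0.28 for NTP303, -1.02 for Actin-97, 0.23 for profilin and -1.04 for pectate lyase (adjusted p = 0.632, 0.00418, 0.286 and 0.0737). In mature RNP 47.2% of calls were higher (15.4% with spike-in scaling and 51% with normexp), and rescaling moved the median probe by -0.81 to 0.37. A CXE carboxylesterase had -2.48 without mature pollen RNP replicate 2.

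RNP of 4 h tubes differed from polysomes in 8195 of 18604 probes (1645 with normexp), 4009 higher and 4186 lower in RNP. The PR-10 type protein NtMALD1b (at least 14.2-fold higher), chloroplast ribosomal protein S16 (5.21 ± 0.59, adjusted p = 9.81e-08) and the psaC product (5.10 ± 0.54) were higher, and nuclear matrix protein 1 (at least 3.04-fold lower, but 0.10 with normexp background correction and medians matched), equilibrative nucleoside transporter 1 (at least 4.82-fold lower) and an endosomal protein (-3.54 ± 0.67) lower. Of 19 cyclin and cell division probes, 11 were higher and 1 lower (11 and 1 adjusted over the list alone), with a relative median of 1.0 (adjusted p = 0.0176, and adjusted p = 0.427 with an estimated correlation, but 0.0748 with normexp). Among them were a cdc2 homolog (2.03 ± 0.31) and a B-type cyclin (at least 5.8-fold higher). RNP of 4 h tubes gave 0.54 for NTP303, -0.33 for Actin-97, 0.96 for profilin and 0.73 for pectate lyase (adjusted p = 0.37, 0.37, 0.000126 and 0.232), but with medians matched profilin -0.24 with normexp background correction. In 4 h RNP 48.9% of calls were higher (7.29% with spike-in scaling and 72.8% with normexp), and rescaling moved the median probe by -1.13 to 1.10. In 4 h RNP the count was 5411 without 4 h tube RNP replicate 2.

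At 24 h RNP and polysomes differed in 7318 of 15805 probes (849 with normexp and 11205 with array weights), 5139 higher and 2179 lower in RNP. Chloroplast ribosomal protein S15 (at least 42.5-fold higher), maturase K (at least 8.94-fold higher) and ATP synthase subunit alpha (5.25 ± 0.40, adjusted p = 4.68e-11) were higher, and hairy root 4 (-4.93 ± 0.72), a photosystem II polypeptide (at least 3.85-fold lower) and methylthioribose kinase (at least 4.26-fold lower) lower. Of 209 cytosolic ribosomal protein probes, 140 were higher and 4 lower (143 and 6 adjusted over the list alone), with a relative median of 0.87 (adjusted p = 7.56e-10, and adjusted p = 0.687 with an estimated correlation). RNP of 24 h tubes gave -1.04 for NTP303, -0.93 for Actin-97, -0.49 for profilin and -0.30 for pectate lyase (adjusted p = 0.0716, 0.01, 0.0279 and 0.643), but with medians matched profilin 0.24 with normexp background correction. In 24 h RNP 70.2% of calls were higher (43.9% with scaling over all probes and 98.8% with spike-in scaling), and rescaling moved the median probe by -0.69 to 1.02. Leaving out an array ended the call of Actin-97 without 24 h tube RNP replicate 2 (adjusted p = 0.0549) and profilin without any 1 of the 4 arrays (adjusted p = 0.0667 to 0.137).

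**Figure D4:**
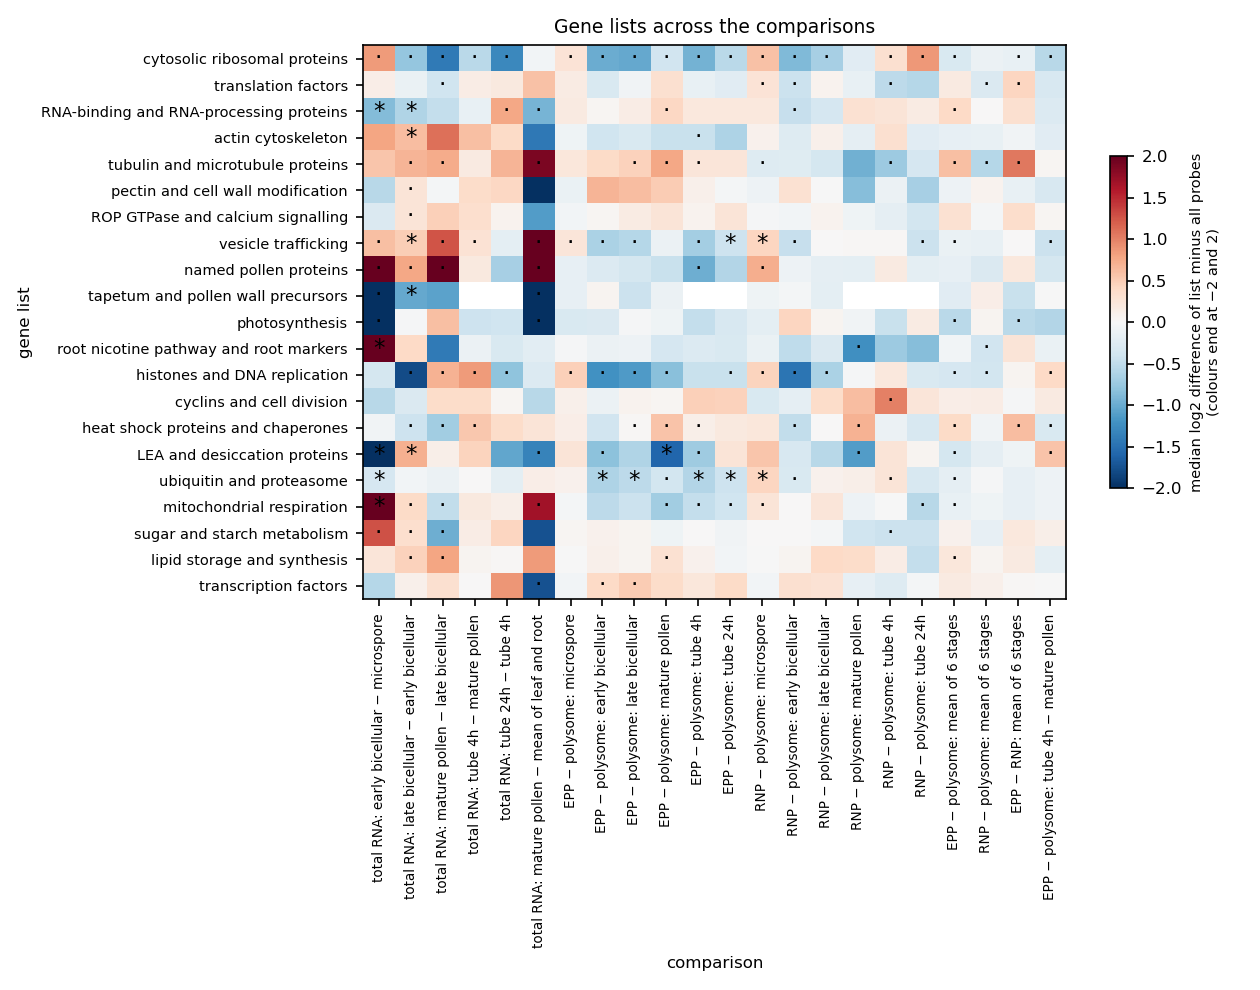
Median log2 difference of each gene list relative to all tested probes (colour) in each comparison, on the main scaling. A dot marks lists called with a preset correlation (145 of 455) and a star those also called with an estimated correlation (18). Of the 145 medians, 30 changed sign on another scaling.

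Averaged over the 6 stages, EPP differed from polysomes in 15988 of 29838 probes (5206 with normexp), 9077 higher and 6911 lower in EPP. Higher with the same sign at all 6 stages were ALG2-interacting protein X (2.24 ± 0.28, adjusted p = 1.42e-07), an RRM-containing RNA-binding protein (2.02 ± 0.22) and S-adenosylmethionine decarboxylase (1.99 ± 0.32) of polyamine synthesis, and lower were chloroplast ribosomal protein S16 (-2.50 ± 0.24), nucleobase-ascorbate transporter 6 (-2.0 ± 0.22) and glutaredoxin (-1.86 ± 0.13). Of 76 RNA-binding and RNA-processing probes, 45 were higher and 14 lower (47 and 15 adjusted over the list alone), with a relative median of 0.39 (adjusted p = 0.00129, and adjusted p = 0.183 with an estimated correlation). The splicing factor SLU7 (1.42 ± 0.26) was one. Of 36 tubulin and microtubule probes, 22 were higher and 4 lower (23 and 4 adjusted over the list alone), with a relative median of 0.61 (adjusted p = 0.00102, and adjusted p = 0.315 with an estimated correlation). These included alpha-tubulin tubA2 (1.49 ± 0.22) and the kinesin tck1 (1.33 ± 0.14). Of 222 cytosolic ribosomal protein probes, 13 were higher and 102 lower (13 and 100 adjusted over the list alone), with a relative median of -0.30 (adjusted p = 7.26e-09, and adjusted p = 0.561 with an estimated correlation). Mean EPP differences were 0.65 ± 0.19 for NTP303, 0.13 ± 0.12 for Actin-97, -0.81 ± 0.07 for profilin and 0.15 ± 0.20 for pectate lyase (adjusted p = 0.00611, 0.361, 1.19e-09 and 0.55). For the mean 56.8% of calls were higher (29% with scaling over all probes and 99.5% with spike-in scaling), and rescaling moved the median probe by -0.54 to 0.99.

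Mean RNP differences from polysomes passed in 13517 of 30544 probes (2937 with normexp), 7405 higher and 6112 lower in RNP. The psaC product (3.40 ± 0.22, adjusted p = 6.65e-13), chloroplast ribosomal protein S16 (3.23 ± 0.24) and late embryogenesis abundant protein 5 (2.29 ± 0.14) were higher, and Bypass1 (-2.21 ± 0.19), citrate synthase (-2.17 ± 0.25) and cytoplasmic phosphoglucomutase (-2.08 ± 0.13) lower. Of 36 tubulin and microtubule probes, 7 were higher and 19 lower (7 and 21 adjusted over the list alone), with a relative median of -0.58 (adjusted p = 0.0424, and adjusted p = 0.975 with an estimated correlation, but 0.146 with quantile). Alpha-tubulin tubA2 (-1.26 ± 0.22) was lower. Of 18 root nicotine pathway and root marker probes, 0 were higher and 5 lower (0 and 5 adjusted over the list alone), with a relative median of -0.38 (adjusted p = 0.0431, and adjusted p = 0.278 with an estimated correlation, but 0.211 with quantile, 0.0878 with normexp and 0.0954 with no filter). Its lower members included delta-tonoplast intrinsic protein (-1.48 ± 0.29), N-methylputrescine oxidase NtMPO2 (-0.99 ± 0.14) and ornithine decarboxylase (-0.88 ± 0.15), of water transport and of nicotine and polyamine synthesis. Mean RNP differences were 0.14 ± 0.19 for NTP303, -0.44 ± 0.12 for Actin-97, 0.05 ± 0.07 for profilin and 0.23 ± 0.20 for pectate lyase (adjusted p = 0.588, 0.00269, 0.601 and 0.37). For mean RNP 54.8% of calls were higher (30.3% with spike-in scaling and 58.3% with normexp), and rescaling moved the median probe by -0.30 to 0.17.

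Set directly against each other over the 6 stages, EPP and RNP differed in 21376 of 30221 probes (7635 with a stricter filter on dim probes), 9641 higher and 11735 lower in EPP. EPP held more of S-adenosylmethionine decarboxylase (3.40 ± 0.32, adjusted p = 1.68e-10), an endosomal protein (3.21 ± 0.27) and a phosphoenolpyruvate translocator (3.18 ± 0.27), and less of chloroplast ribosomal protein S16 (-5.73 ± 0.24), the psaC product (-4.62 ± 0.22) and ORF45 (-4.03 ± 0.40). Of 36 tubulin and microtubule probes, 23 were higher and 6 lower (23 and 6 adjusted over the list alone), with a relative median of 1.06 (adjusted p = 0.00193, and adjusted p = 0.472 with an estimated correlation). Members were alpha-tubulin tubA3 (2.26 ± 0.20) and a microtubule bundling polypeptide (2.07 ± 0.14). The followed genes gave 0.51 ± 0.19 for NTP303, 0.57 ± 0.12 for Actin-97, -0.86 ± 0.07 for profilin and -0.09 ± 0.20 for pectate lyase (adjusted p = 0.021, 0.000108, 3.67e-11 and 0.708). Between EPP and RNP 45.1% of calls were higher (13.2% with normexp and 94.4% with spike-in scaling), and rescaling moved the median probe by -0.67 to 1.29. The threshold was missed by NTP303 without microspore RNP replicate 2 (adjusted p = 0.0711).

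Whether the difference between EPP and polysomes itself changed was tested between mature pollen and 4 h tubes, and 395 of 21664 probes (133 with quantile and 4319 with array weights) passed, 225 with a larger and 170 with a smaller EPP difference in tubes. The EPP difference was smaller in tubes for the glycine-rich protein-like transcript (-2.76 ± 0.39, adjusted p = 0.000556) and the mitochondrial small heat shock protein (-2.66 ± 0.64). The largest rises, such as those of Hairy meristem and patatin-like protein 2, rested on 2 or 3 of 8 arrays above background, so no size is given. Of 60 vesicle trafficking probes, 0 were higher and 2 lower (0 and 2 adjusted over the list alone), with a relative median of -0.43 (adjusted p = 0.000108, and adjusted p = 0.0897 with an estimated correlation, but 0.064 with quantile). For this change the followed genes gave -0.67 ± 0.67 for NTP303, -0.98 ± 0.41 for Actin-97, 0.14 ± 0.26 for profilin and -0.17 ± 0.70 for pectate lyase (adjusted p = 0.633, 0.211, 0.809 and 0.918). Over all 6 stages, 15130 of 29838 probes had EPP differences that varied (380 with normexp, 3675 with array weights, 7057 with quantile normalization, 24777 with spike-in scaling and 10438 over 5 stages without microspores, a choice made after seeing the data), including NTP303 (adjusted p = 3.02e-05), Actin-97 (0.0408), profilin (0.00155) and pectate lyase (0.00254). For the change between mature pollen and tubes, 57% of calls were higher (1.17% with spike-in scaling and 55.6% with the deposited matrix), and rescaling moved the median probe by -1.61 to 0.94. Its count was 51 to 187 with any 1 of its 8 arrays left out. No probe passed in limma with normexp background correction (804 at unadjusted p under 0.05), only its own groups in the fit (6280 at unadjusted p under 0.05) or slide as a fixed block (1474 at unadjusted p under 0.05). Without any 1 of the 8 arrays but mature pollen polysome replicate 2, the mitochondrial small heat shock protein lost its call. Its change was then -2.69 to -2.35.

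**Figure D5:**
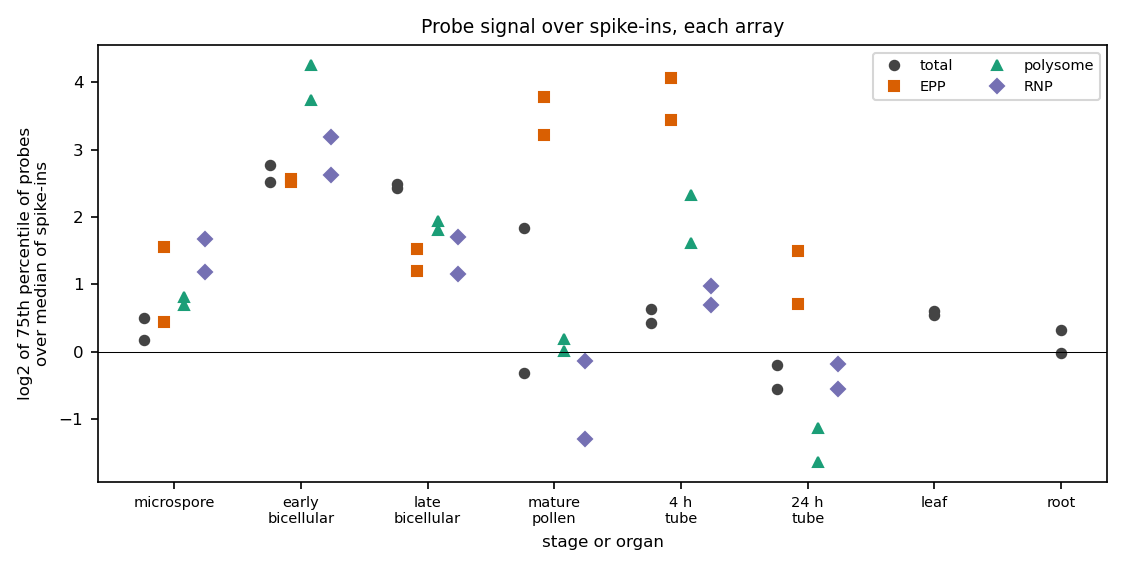
Log2 of the 75th percentile of the 7616 probes used for scaling over the median of the spike-in controls, for each array (points), by stage and fraction. EPP arrays of mature pollen averaged 3.50 and polysome arrays 0.0995, with 2 arrays each.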

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

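A pair of results were set apart because an effect differed between groups by a test of the difference itself, and the test of unequal spike-in signal was chosen only after its result was seen. The difference between EPP and polysomes changed from mature pollen to 4 h tubes in 395 probes, and in 51 to 187 with 1 of its 8 arrays left out. In limma 0 passed with normexp, with only its own groups in the fit and with slide as a fixed block (804, 6280 and 1474 at unadjusted p under 0.05). The difference varied over the 6 stages in 15130 (380 with normexp, 3675 with array weights, 7057 with quantile normalization, 24646 with no filter, 24777 with spike-in scaling and 10438 over 5 stages without microspores).

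The genes with the largest such change are given with their EPP difference in mature pollen and then in tubes. It fell for an early light inducible protein (2.15 and -3.28, change -5.43 ± 1.26, adjusted p = 0.0228), a glycine-rich protein-like transcript (3.95 and 1.19, change -2.76 ± 0.39, adjusted p = 0.000556), a mitochondrial small heat shock protein (3.24 and 0.58, change -2.66 ± 0.64, adjusted p = 0.0271), a phosphosulfolactate synthase-related protein (3.38 and 1.22, change -2.16 ± 0.43, adjusted p = 0.0104) and the GTPase gene rac4 (1.95 and -0.0188, change -1.96 ± 0.52, adjusted p = 0.0432, but 0.31 with normexp background correction and medians matched). The 5 with the largest fitted rise lay above background on 2 or 3 of the 8 arrays. Their changes, 4.59 for Avr9, 4.52 for Hairy meristem, 4.25 for patatin-like protein 2, 3.73 for the organelle RNA polymerase gene rpoT1-tom and 3.61 for a stearoyl-ACP desaturase, rest on signals at background and measure no size. Of the 10, only the glycine-rich protein-like transcript passed without each of the 8 arrays in turn, and no explanation was tested for these genes.

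Microspore libraries formed pairs that did not follow their labels. The libraries labelled polysome replicate 2 and RNP replicate 1 correlated across probes at 0.982, and those labelled EPP replicate 2 and RNP replicate 2 at 0.991, against 0.839 and 0.903 for the polysome and the RNP replicates. Each closest pair shared a slide and these replicates did not, but the EPP replicates shared one too, at 0.925. The difference between the 2 slides correlated at 0.679 with RNP minus polysome of early bicellular pollen on another slide. A slide effect stays open, as both differences went with more probes above background. Exchanged labels of polysome replicate 2 and RNP replicate 2 could also account for the pairs. RNP minus polysome correlated with that of early bicellular pollen at -0.69 for replicate 2 and 0.555 for replicate 1. EPP replicate 1 lay as near to polysome replicate 1 (0.995) whatever the labels, so a weak separation of fractions at this stage stays open. The labels were kept, and no biological explanation was tested.

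The 75th percentile of probe signal over the spike-ins was 3.40 log2 higher in EPP than in polysome arrays of mature pollen (3.50 ± 0.395 against 0.0995 ± 0.132, SD, n = 2), 1.79 higher in 4 h tubes and 2.49 in 24 h tubes, and it differed by -1.45 and -0.51 in early and late bicellular pollen. The spike-in signal itself was argued against as the source, since it gave 14.9%, 24.1% and 25.6% of the difference in the 3 later stages. Slide was argued against too, since with slide as a block the difference was 2.88 ± 0.72 (95% interval 1.04 to 4.72) over mature pollen and 4 h tubes. A larger share of messenger RNA in the EPP preparations of mature pollen and tubes is a hypothesis consistent with these values, but labelling and the amount of RNA other than messenger were not measured. Because of this shift, spike-in scaling made 19579 of 19611 called probes higher in EPP of mature pollen.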

How the results depend on the processing

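Here total RNA steps are named by their later stage, EPP and RNP stand for their differences from polysomes, leaf and root for mature pollen against both, the tube change for the change of the EPP difference from mature pollen to 4 h tubes, and unadjusted for the count of limma at an unadjusted p under 0.05. Slide as a fixed block, the averages without microspores and the fit without microspore fractions were chosen after seeing the data. Quantile normalization gave 5244 for early EPP, 3491 for 4 h EPP, 7 for microspore RNP, 133 for the tube change and 7057 for the 6-stage test. Normexp background correction gave 8144 for early total, 840 for late total, 1878 for 4 h total, 2060 for 24 h total, 15543 for leaf and root, 0 for microspore EPP (581 unadjusted) and 1491 for early EPP. It also gave 965 for late EPP, 752 for 4 h EPP, 91 for 24 h EPP, 0 for microspore RNP (605 unadjusted), 1071 for early RNP, 1108 for late RNP and 1040 for mature RNP. It gave 1645 for 4 h RNP, 849 for 24 h RNP, 5206 for mean EPP, 2937 for mean RNP, 0 for the tube change (804 unadjusted) and 380 for the 6-stage test. Scaling over all probes gave 0 for microspore RNP (2584 unadjusted). Spike-in scaling gave 3089 for late total, 1794 for 4 h total, 6129 for 24 h total, 1 for microspore EPP, 5427 for early EPP, 991 for late EPP and 19611 for mature EPP. It also gave 16422 for 4 h EPP, 15908 for 24 h EPP, 0 for microspore RNP (880 unadjusted), 2888 for late RNP, 2572 for the tube change and 24777 for the 6-stage test. No filter on dim probes gave 30991 for early total, 24687 for mature EPP, 17336 for 24 h EPP and 24646 for the 6-stage test. A stricter filter on dim probes gave 8013 for mature total, 10021 for leaf and root, 0 for microspore EPP (1939 unadjusted), 2636 for 24 h EPP, 4752 for 24 h RNP, 7233 for mean EPP and 6218 for mean RNP. It also gave 7635 for mean EPP against RNP, 165 for the tube change and 5171 for the 6-stage test. Array weights gave 13377 for late total, 8197 for mature total, 1432 for 4 h total, 0 for microspore EPP (319 unadjusted), 13517 for late EPP, 11598 for mature EPP and 9981 for 4 h EPP. It also gave 7983 for 24 h EPP, 0 for microspore RNP (299 unadjusted), 17117 for early RNP, 11205 for 24 h RNP, 4319 for the tube change and 3675 for the 6-stage test. Only its own groups in the fit gave 11981 for late total, 0 for mature total (7582 unadjusted), 0 for 4 h total (882 unadjusted), 0 for microspore EPP (206 unadjusted), 0 for 4 h EPP (8607 unadjusted), 2636 for 24 h EPP and 0 for microspore RNP (198 unadjusted). It also gave 15950 for early RNP and 0 for the tube change (6280 unadjusted). The replicate number as a block gave 6 for microspore RNP. Slide as a random block gave 5 for microspore RNP and 623 for the tube change. The deposited matrix gave 846 for microspore EPP and 726 for microspore RNP. An added minimum log2 of 1 gave 2757 for 24 h EPP, 3845 for mean EPP, 4304 for mean RNP and 10623 for mean EPP against RNP. Slide as a fixed block gave 556 for 4 h total, 0 for microspore EPP (280 unadjusted), 0 for mature EPP (5552 unadjusted), 0 for 4 h EPP (5027 unadjusted), 7152 for 24 h EPP, 0 for microspore RNP (4067 unadjusted) and 2145 for mature RNP. It also gave 2564 for 4 h RNP and 0 for the tube change (1474 unadjusted). The microspore fraction arrays left out gave 6530 for 24 h EPP and 2319 for the tube change. Other counts of these settings lay within 1.5 times the main count. The cause of these shifts was not tested, except that no filter tests more probes, a stricter filter tests fewer, and leaving out an array or groups lowers the degrees of freedom. Leaving out an array called 0 probes for microspore RNP without microspore polysome replicate 1 (3621 unadjusted). With each array left out in turn, counts ran from 12340 to 17638 for the 6-stage test, 6140 to 7453 for early EPP, 3656 to 4855 for late EPP, 4430 to 5128 for mature EPP, 14265 to 16549 for mean EPP, 1 to 3939 for microspore EPP, 1724 to 2463 for 24 h EPP and 1825 to 4904 for 4 h EPP. Likewise they ran from 51 to 187 for the tube change, 20490 to 21645 for mean EPP against RNP, 4365 to 4814 for early RNP, 4725 to 5032 for late RNP, 6727 to 7359 for mature RNP, 12630 to 14762 for mean RNP, 0 to 2758 for microspore RNP and 5208 to 5420 for 24 h RNP. For the rest they ran from 5411 to 6801 for 4 h RNP, 11566 to 12252 for early total, 3857 to 4799 for late total, 12312 to 14198 for mature total, 23065 to 24817 for leaf and root, 7956 to 8271 for 24 h total and 4056 to 7690 for 4 h total. Signs of named genes turned on other settings, for scalings after the median of all tested probes was set to that of the main scaling. With quantile normalization, NTP303 was at -0.00643 (late total), -1.13 (mature total), -0.00976 (4 h total), 0.25 (4 h EPP), 0.33 (24 h EPP) and -0.51 (4 h RNP). Pectate lyase was at -0.95 (mature total), 0.58 (mature EPP), 0.74 (4 h EPP), 0.31 (24 h EPP), -0.34 (4 h RNP), 0.43 (24 h RNP), 0.52 (mean EPP against RNP) and 0.21 (the tube change). Actin-97 was at 1.16 (4 h EPP) and 0.53 (24 h EPP). With normexp background correction, profilin was at 0.12 (early total), -0.0291 (late total), -1.70 (mature total), 0.15 (microspore EPP), 0.13 (mature EPP), 0.43 (24 h EPP), -0.23 (mature RNP), -0.24 (4 h RNP), 0.24 (24 h RNP), -0.15 (mean RNP) and -0.83 (the tube change). NTP303 was at -0.91 (mature total), 0.12 (4 h EPP), 0.000949 (24 h EPP), -0.12 (late RNP), -0.69 (4 h RNP) and -0.12 (mean RNP). Pectate lyase was at -1.16 (mature total), 1.17 (mature EPP), 0.16 (4 h EPP), -0.50 (4 h RNP), 0.42 (24 h RNP), -0.0450 (mean RNP) and 0.68 (mean EPP against RNP). Actin-97 was at 0.19 (microspore EPP), 0.53 (4 h EPP), 0.36 (24 h EPP), 0.10 (microspore RNP) and -0.35 (early RNP). Vetispiradiene synthase was at 0.10 (early EPP). Dehydrin-like protein was at 0.0202 (mature EPP). GTPase Sar1BNt was at 0.0503 (24 h EPP). Nuclear matrix protein 1 was at 0.10 (4 h RNP). Rac4 was at 0.31 (the tube change). With slide as a random block, pectate lyase was at 0.0133 (microspore EPP). Profilin was at 0.0300 (microspore EPP). With the deposited matrix, NTP303 was at -0.76 (mature total), -0.48 (4 h total), -0.14 (24 h total), 0.52 (4 h EPP), 1.06 (24 h EPP) and -0.52 (4 h RNP). Pectate lyase was at -1.18 (mature total), -0.23 (24 h total), 2.0 (mature EPP), 0.58 (4 h EPP), 1.35 (24 h EPP), 0.0189 (late RNP), -0.27 (4 h RNP), 0.41 (24 h RNP) and 0.46 (mean EPP against RNP). Profilin was at -0.32 (mature total). Actin-97 was at -0.25 (early EPP), 0.94 (4 h EPP), 0.51 (24 h EPP) and -0.65 (early RNP). Vetispiradiene synthase was at 0.48 (early EPP). With slide as a fixed block, NTP303 was at 0.68 (microspore EPP). Pectate lyase was at 0.81 (microspore EPP). Profilin was at 0.15 (microspore EPP). With the 5 stages without microspores, profilin was at -0.0163 (mean RNP). Pectate lyase was at 0.00620 (mean EPP against RNP). Leaving out an array turned the sign of named genes that had not passed, with ranges of -0.29 to 0.28 for profilin (microspore EPP), -0.0369 to 0.0127 for Actin-97 (microspore EPP), -0.92 to 1.42 for NTP303 (microspore RNP), -0.75 to 1.38 for pectate lyase (microspore RNP), -0.0306 to 0.32 for pectate lyase (mean EPP), -0.0539 to 0.34 for NTP303 (mean RNP), -1.53 to 0.81 for NTP303 (microspore EPP) and -1.30 to 0.82 for pectate lyase (microspore EPP). More such ranges were -0.26 to 0.0867 for pectate lyase (mean EPP against RNP), -0.0531 to 0.14 for Actin-97 (early RNP), -0.25 to 0.15 for pectate lyase (late RNP), -0.000862 to 0.41 for NTP303 (late RNP), -0.13 to 0.26 for NTP303 (4 h total), -0.0127 to 0.0925 for NTP303 (mature EPP), -0.31 to 0.00648 for Actin-97 (4 h EPP) and -0.42 to 0.0788 for pectate lyase (the tube change). Of 455 tests of lists, 145 were called with the preset correlation and 18 with an estimated correlation. Of the 145, 113 were kept with quantile normalization, 115 with normexp background correction, 127 with scaling over all probes, 108 with no filter on dim probes and 145 with the replicate number as a block. Scan day as a block was not run. The brighter side was not above background in 36.2% of normexp calls lower in mature EPP and 33.4% of those higher for leaf and root. The share was 12% (higher, mature total) and 1.23% (lower, mean EPP against RNP).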

Other observations

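More lists were called in total RNA with the preset correlation, and the test of array scaling below was chosen only after its result was seen. From microspores to early bicellular pollen, of 62 sugar and starch metabolism probes, 30 were higher and 19 lower (30 and 19 adjusted over the list alone), with a relative median of 1.28 (adjusted p = 0.00866, and adjusted p = 0.319 with an estimated correlation). In the same step, of 15 root nicotine pathway and root marker probes, 9 were higher and 4 lower (10 and 4 adjusted over the list alone), with a relative median of 2.23 (adjusted p = 0.00173, and adjusted p = 0.0256 with an estimated correlation). The members higher in early bicellular pollen included A622 (at least 4.32-fold higher) and quinolinate phosphoribosyltransferase (at least 5.13-fold higher), enzymes of nicotine synthesis. From late bicellular to mature pollen, of 57 sugar and starch metabolism probes, 6 were higher and 38 lower (6 and 38 adjusted over the list alone), with a relative median of -0.97 (adjusted p = 0.0278, and adjusted p = 0.415 with an estimated correlation).

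Transcripts described as plastid or mitochondrial were noticed among those highest in RNP, and such a class held back from polysomes was taken as a hypothesis. A list of 31 such probes had 21 higher and 2 lower in RNP over the 6 stages, but it held genes that raised the hypothesis. The 16 members not among the named genes had a relative median of 0.16, 7 higher and 2 lower, with p = 0.0935 by the preset and p = 0.322 by an estimated correlation, which leaves the hypothesis open. Over the 6 stages in order, the relative medians of these members were 0.24, 0.0249, -0.0663, 0.14, 0.45 and 2.30, the last, in 24 h tubes, with p = 0.0208 by an estimated correlation, not adjusted over stages. Scaling of the arrays stays open as well. Of settings that can move a relative median, normexp gave the lowest, 0.31 for the list and -0.064 for members not named. Nuclear genes share several descriptions.

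Of 100 groupings within stages, only the real one called as many probes for each average, which argues against chance without excluding it. The real counts and the highest of the other groupings were 15988 and 11681 for EPP against polysomes, 13517 and 9348 for RNP against polysomes, and 21376 and 20132 for EPP against RNP.

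Over 325 pairs of groups the differences between replicates correlated across probes at a median of 0.0105, from -0.655 to 0.519, and 77 pairs lay above 0.1. Most of these pairs join different stages, so the median cannot tell whether fractions of the same stage were paired by replicate number. The weight of the total RNA arrays of mature pollen was the lowest of any group, and their correlation was 0.877.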
